A study of Mus musculus with 2 samples.

How the data were processed

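RNA from the corneal epithelium of C57BL/6 mice was measured on microarrays in 2 samples, 1 from injured eyes and 1 from uninjured fellow eyes. Per the labels, 2 µg of each RNA was amplified and labelled with biotin before hybridisation. The deposited table holds 1 column per sample and 65952 rows, and the authors' values are log2 intensities: they lie between 2.54 and 14.1 with medians of 5.44 in the injured and 5.43 in the uninjured array. Per the submitters' processing notes the tool was Agilent Feature Extraction 9.1, whereas the row identifiers have the form of transcript clusters of a transcriptome array and the label is biotin. The background correction, the summary of probes into rows, the between-array normalization and the genome build are not given in the sources used here. The 2 columns differed by 0.0135 in their median and by 0.00510 in their 75th percentile, less than the 0.1 set beforehand for a table already normalized between arrays, so the values were kept as deposited. No scanner files were used here, so no detection or saturation call stands behind a value.

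Rows were named from the platform's annotation, with older symbols updated through gene identifiers and synonyms of the RefSeq annotation of GRCm38.p6, which also gave each gene's biotype and which genes neighbour each other. Of the rows, 31070 carried 1 gene, 1676 carried several and were left unnamed, and 33206 are unnamed here, which does not make them rows without a gene. The named rows cover 30544 different genes. Long non-coding RNAs were genes with the RefSeq biotype lncRNA or antisense RNA. A row was kept when the brighter of its 2 values was at or above 5.44, the median of all values in the table, and this left 19411 genes measured and 11133 genes out. Where a gene had several kept rows, the row with the highest mean over both arrays stood for it, a choice that does not look at the difference.

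With 1 array in each group there is no spread between samples, so no test was run and no p-value is given, and every difference is without a replicate check. A gene was counted as higher or lower when its log2 value differed by 1 or more, which is 2-fold, injured minus uninjured. Each of 46 gene lists was fixed before the data were examined and described by the median difference of its measured members. That median was placed among 10000 random lists of the same size, matched on mean expression in 20 bins, and a list outside the central 95% was called higher or lower. Of the 46 lists 2.3 are expected outside by chance if their members vary independently, which genes controlled together do not. No correction was made for the number of lists. The percentiles describe these 2 arrays and carry no error between animals. Of 926 different genes in the lists, 693 were measured, 107 lay below the low-signal filter, 68 occurred only on rows with several genes and 58 had no row. One human symbol in a list was dropped because it is an alias of an unrelated mouse gene.

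Genes were named by a rule fixed before the data were examined. It took up to 4 members at least 2-fold apart, by size of difference, from each list outside the central 95%, and up to 2 from every other list. It added the 10 highest and 10 lowest genes, and the 5 highest and 5 lowest long non-coding RNAs, whose brighter value was above the 75th percentile of the table. It ended with a short set named whatever their values: Krt12, Pax6, Krt14, Trp63, Mki67, Krt6a, Krt16, Fn1, Mmp9, Il1b, S100a8, Aldh3a1, Tkt, H19, Neat1, Malat1, Xist, Ddx3y and the RNA of the series title. The rule gave 132 genes with a value. Members named to complete a count of 5 or fewer were chosen after their values were seen, namely Barx2, Id1, Aldh1a3, Pkm, Muc15, Fut9, Krt7, Lce3a, Evpl, Igfbp2, Krt19, Krt15, Tgfbr2, Ccn2, Ccn1, Tgfbi, Klf4, Myc, Fosl1, Il1f8, Pglyrp1, Defb1, Oasl1, Gstm1, Nqo1, Hspb1, Scnn1a, Kdm5d, Uty and Eif2s3y. Wincr1, Krt1, Krt4, Krt10, Krt13, Ly6g and Tyrobp lie outside the rule and were also chosen after their values were seen. Of the others, Krt6a shares its row with Krt6b, Tkt and H19 share theirs with a microRNA, S100a8 fell below the low-signal filter and Ddx3y had no row. No row carries the name of the RNA in the series title, which is not analysed here.

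The error that the design can show is the disagreement between rows of one gene within these arrays. The SD of the log2 difference within a gene was 0.254 over 485 rows of 230 genes. For the 14919 rows with both values below the 25th percentile of the table, the SD of the difference was 0.179. That choice of rows removes large differences, so this SD is too small to serve as an error. The number of arrays limits the precision of every comparison.

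The alternatives were quantile normalization, equal medians, equal 75th percentiles, a loess of the difference on the mean with a span of 0.3, other low-signal filters, other choices of row, thresholds of 1.5-fold and 4-fold, a constant of 13.9 added on the linear scale, and other ways to summarise or draw lists. Drawing the random lists from protein-coding genes only was added after seeing the data. The procedures were tested on simulated data for the comparison of injured with uninjured, over 19235 genes built on the real mean values with a noise SD of 0.2. All 100 genes changed by a log2 of 1.5 and all 100 changed by 3 were called in the right direction, and 0 of 19035 unchanged genes were called. That outcome follows from the settings. The noise lay far below the threshold of 1 and below the 0.254 measured between rows of one gene. It held no spread between mice, and the changed genes were picked from brighter genes with 1 row. So it checks the procedure and gives no rate of false calls for the real arrays. Of 500 lists of 20 unchanged genes 4.80% were called. Calculations used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and statsmodels 0.14.6, and plots were drawn with matplotlib 3.10.9.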

Results

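Gene expression was measured in the corneal epithelium of C57BL/6 mice aged 8 weeks during the repair of an epithelial wound. The epithelium of 1 eye was taken off to its full depth as far as the limbus, the border zone that holds the corneal epithelial stem cells, with a 0.5 mm rust ring remover. About 48 hours later, when 10% of the wound area was still open, the epithelium of the injured eyes and of the fellow eyes was collected. There was 1 injured and 1 uninjured array, and the number of mice behind each is not given in the sources used here. The deposited values are log2 intensities of 65952 rows, of which 19411 genes passed the low-signal filter. With 1 array per group every difference stands without a replicate check, so genes are called higher or lower by size alone and each value describes these 2 arrays.

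The comparison asks which genes and long non-coding RNAs differ between the epithelium that is closing a wound and the intact epithelium. In the injured epithelium 805 genes were at least 2-fold higher and 756 at least 2-fold lower, while 17850 were less than 2-fold apart. Among genes whose brighter value was above the 75th percentile of the table, the highest were Dynap, a dynactin-associated protein, by 7.20 on the log2 scale, and Ppbp, the precursor of the chemokine Cxcl7, by 7.19 (146-fold). They were followed by the small proline-rich cornified envelope genes Sprr2b (5.55), Sprr2f (5.53) and Sprr1b (5.30), the plasminogen activator inhibitor Serpinb2 (5.18), the prostaglandin synthase Ptgs2 (4.71), the matrix glycoprotein Tnc (4.53), the wound keratin Krt16 (4.45) and the proliferin Prl2c2 (4.42). The lowest were 2 genes for Ly6-type proteins, Lypd2 with a log2 difference of -7.49 (180-fold) and Slurp1 with -6.61 (97.7-fold). Next came the fatty acid hydroxylases Cyp4a12b (-6.54) and Cyp4a12a (64.0-fold), Mgarp (-5.67), the glycogen-targeting phosphatase subunit Ppp1r3c (-5.67), Fam169a (-5.57), the cation channel Trpm3 (-5.51), the pseudogene Gm12837 (-4.96) and Erich5 (-4.92). The Cyp4a12, Sprr2 and Prl2c families hold near-identical copies, so the share of the signal that belongs to each member is uncertain. The dimmer value lay below the low-signal level of 5.44 for 5 of the 10 highest and 4 of the 10 lowest, Dynap (4.93), Prl2c2 (3.90) and Gm12837 (3.71) among them, so the size of these differences is uncertain. With a constant added before the log2 step Dynap was 101-fold and Ppbp 118-fold higher, so their order is not settled. Gm12837 was then 15.6-fold and Erich5 28.1-fold lower, so their order is not settled either. Of the 132 genes named by rule, a further 11 had a dimmer value below that level, so their size is uncertain too: Ces1d, Xlr4d-ps, Emx2os, Dcn, Il1b, Col8a1, Adamts1, Defb14, Krtdap, Il24 and Fst. At 4-fold or more, 137 genes were higher and 151 lower, and at 16-fold or more 16 were higher and 22 lower.

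**Figure D1:**
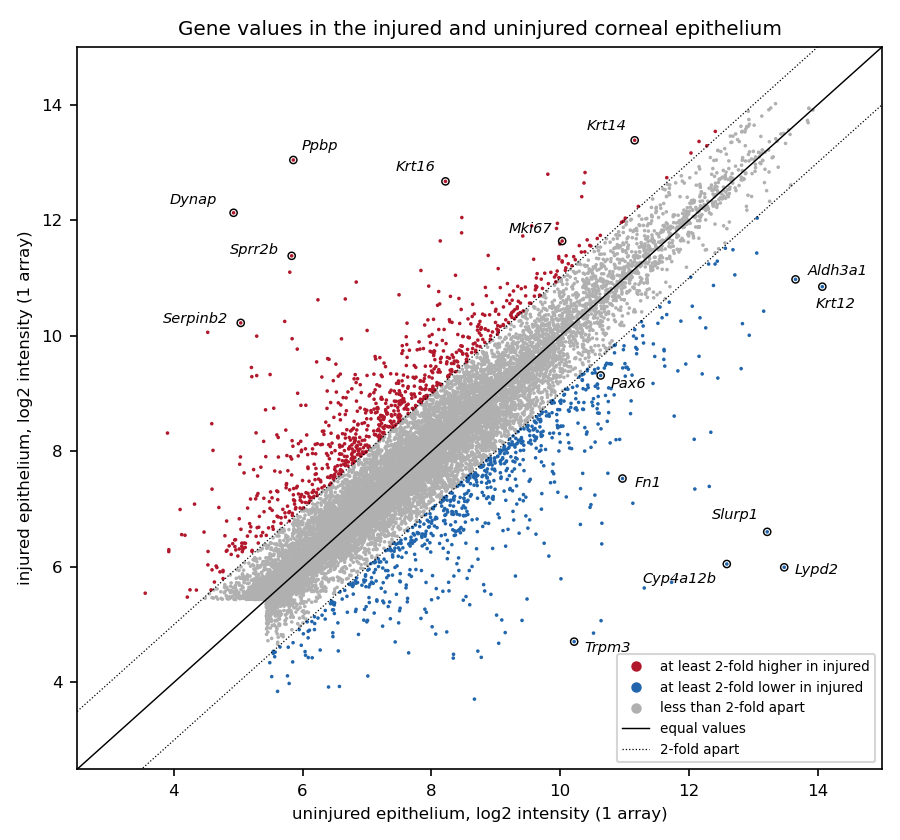
Log2 intensity of 19411 genes in the uninjured (x axis) and the injured (y axis) corneal epithelium, 1 array each, with 1 point per gene. Red points are the 805 genes at least 2-fold higher in the injured epithelium and blue points the 756 at least 2-fold lower. Dynap and Ppbp lie farthest above the line of equal values and Lypd2 and Slurp1 farthest below it.

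Genes of the differentiated corneal epithelium were lower in the injured eye. Of 22 measured identity genes 10 were at least 2-fold lower and 2, Barx2 and Id1, at least 2-fold higher, with a median difference of -0.86, below all of the 10000 matched random lists (percentile 0). Besides Lypd2 and Slurp1, the carboxylesterase Ces1d (-4.01) and the water channel Aqp5 (-3.87) were lower. Krt12, the keratin specific to the corneal epithelium, was lower (-3.22), the corneal crystallin Aldh3a1 6.41-fold lower (-2.68) and Pax6, the transcription factor that specifies the eye, 2.49-fold lower (-1.32). The uninjured value of Krt12, 14.07, is the highest of that array and no saturation call was used here, so its difference can be understated. The list of corneal crystallins and metabolic enzymes held both directions, with Aldh1a1 (-3.30) and Aldh3a1 lower, Aldh1a3 and Pkm higher, and a median of 0.19 within the range of random lists (percentile 82.6). Desmosome and junction genes had a median of -0.34 (percentile 0), although only 2 of 23 were at least 2-fold lower, the desmogleins Dsg1a (-2.87) and Dsg1b (-2.15), and the tight junction gene Cldn1 was higher (1.75). Of 12 mucin and glycocalyx genes the membrane mucin Muc4 (-1.62), Muc20 (-1.42) and Muc15 were at least 2-fold lower and the fucosyltransferase Fut9 higher, while the list median of 0.03 stayed within random lists (percentile 37.1) and lay below them (-0.29) with only genes whose brighter value was above the 75th percentile. Integrin, laminin and hemidesmosome genes also stayed within them (median -0.14, percentile 3.52), though below random lists not matched on expression, and Itga5, a subunit of the fibronectin receptor, was the 1 member of 20 past 2-fold (1.02).

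Keratins and envelope proteins of stressed and stratifying epithelium were higher. Of 9 measured genes in the list of wound and hyperproliferation keratins 5 were at least 2-fold higher, with a median of 1.34 (percentile 100). These were Krt16 by 4.45, Krt17 by 3.58, Krt18 by 3.22, Krt8 by 1.52, and Krt7. The list also holds Krt1, Krt4, Krt10 and Krt13, keratins of differentiated epithelia, and these 4 were less than 2-fold apart. Cornified envelope genes had a median of 1.12 (percentile 100), and 12 of 22 were at least 2-fold higher, among them Krtdap (3.89), while Lce3a and Evpl were at least 2-fold lower. Basal and limbal progenitor markers had a median of 0.30 (percentile 99.2) with 5 of 18 at least 2-fold higher and 2 lower. Within that list the interferon-induced membrane protein gene Ifitm3 (3.31), the basal keratin Krt14 (2.23) and the tetraspanin Cd63 (1.56) were higher, as were Igfbp2 and Krt19. The growth factor receptor regulator Lrig1 (-1.79) and the basal keratin Krt15 were lower, and Trp63, the transcription factor of stratified epithelial progenitors, differed by -0.36. The median of this list was 0.0935, within random lists, without the members that other lists share, and 0.13 without the low-signal filter.

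Genes of cell division, DNA replication and ribosome assembly were higher. Of 27 mitosis genes 26 were at least 2-fold higher, with a median of 1.70 (percentile 100). The kinetochore motor Cenpe (2.42), the checkpoint kinase Bub1 (2.36), the anaphase activator Cdc20 (2.26) and Hmmr (2.26) led them, and the proliferation marker Mki67 was higher by 1.61. DNA replication genes had a median of 0.99 (percentile 100) with 12 of 25 at least 2-fold higher and 0 lower, led by the ribonucleotide reductase subunits Rrm2 (1.59) and Rrm1 (1.42) and the helicase subunits Mcm4 (1.41) and Mcm5 (1.38). Ribosome biogenesis genes had a median of 1.09 (percentile 100) with 12 of 19 at least 2-fold higher and 0 lower, among them the nucleolar proteins Npm1 (1.59), Rrp1b (1.41), Nop58 (1.37) and Nolc1 (2.83-fold). Ribosomal protein genes had 0 of 12 past 2-fold and a median of 0.19 (percentile 86.0). Among 14 cell cycle inhibitors and p53 targets, Cdkn1b, an inhibitor of cyclin-dependent kinases, was at least 2-fold lower (-1.11), and the list median of -0.02 lay within random lists (percentile 25.5).

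**Figure D2:**
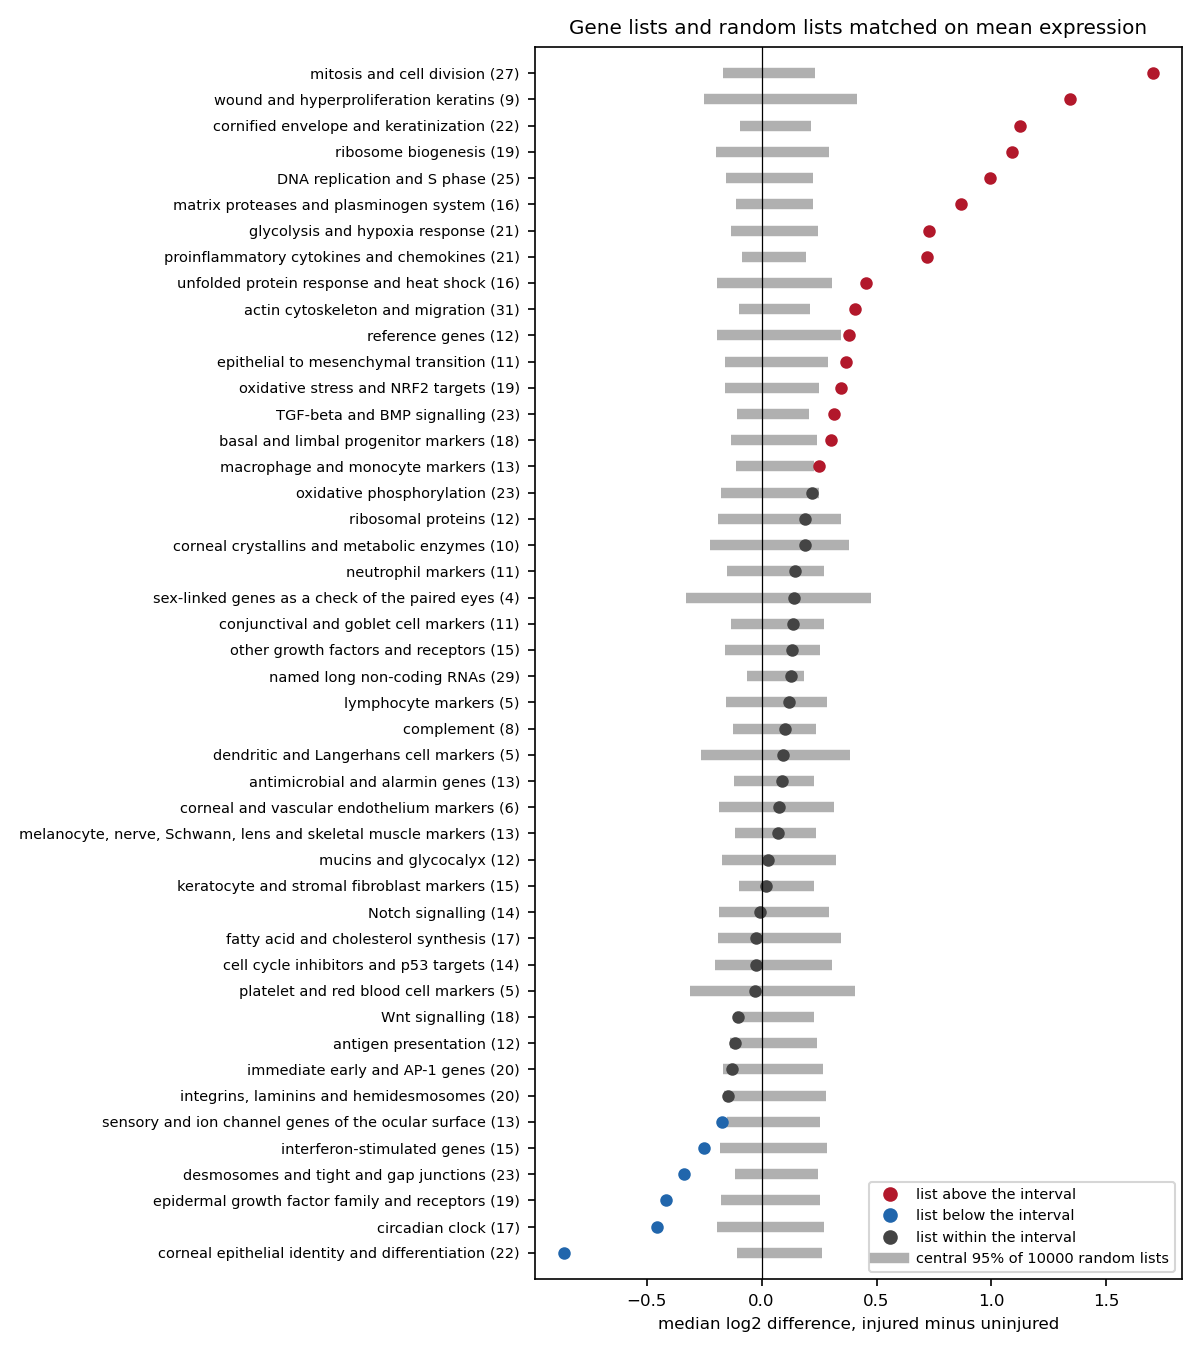
Median log2 difference of each of 46 gene lists, injured minus uninjured, on the x axis, with the number of measured genes after each name and 1 array per group. Grey bars are the central 95% of 10000 random lists matched on mean expression. The medians run from -0.86 for corneal identity to 1.70 for mitosis, and 16 lists lie above and 6 below the grey bars.

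Genes of cell movement and of matrix remodelling were higher. In the actin and migration list 9 of 31 genes were at least 2-fold higher and 0 lower, with a median of 0.41 (percentile 99.99): Msn, which links actin to the membrane, by 4.38 (20.9-fold), the actin crosslinker Actn1 by 4.10 (17.1-fold), the annexin Anxa3 by 2.65 and the actin bundler Fscn1 by 2.23. Of 16 proteases, inhibitors and plasminogen genes 8 were at least 2-fold higher and 0 lower, with a median of 0.87 (percentile 100). Next to Serpinb2 stood the metalloproteases Adam8 (3.33) and Adamts1 (2.37) and the urokinase receptor Plaur (1.97), whereas the gelatinase Mmp9 differed by 0.40. In the TGF-beta and BMP list (median 0.31, percentile 99.8) 5 of 23 genes were at least 2-fold higher and 4 lower. The activin antagonist Fst (4.08) and the matrix protein Thbs1 (2.43) were higher, with the receptor Tgfbr2, Id1 and Ccn2. Id2, an inhibitor of differentiation (-2.02), and the receptor Tgfbr1 (-1.39) were lower, with Ccn1 and Tgfbi. Epithelial to mesenchymal transition genes had a median of 0.37 (percentile 99.1) with 8 of 11 less than 2-fold apart: Tnc and the smooth muscle actin Acta2 (2.25) were higher, and fibronectin, Fn1, was 10.8-fold lower (-3.44). With only genes whose brighter value was above the 75th percentile, the median of this list was 0.44, within random lists.

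Genes of the epidermal growth factor family and its regulators had a median of -0.42 (percentile 0.0100), yet 17 of 19 were less than 2-fold apart. The exceptions were Lrig1 and the phosphatase Dusp4, which was higher (1.13), and with the mean in place of the median this list lay within random lists at -0.28. Other growth factors and receptors had a median of 0.13 (percentile 81.1), with the insulin-like growth factor binding protein Igfbp3 at 3.85 and Vegfa at 1.26. The Wnt list (median -0.10, percentile 3.42) held 2 of 18 genes at least 2-fold lower, the secreted antagonists Dkk3 (-1.31) and Sfrp1 (-1.27), and lay below random lists (-0.48) with only genes whose brighter value was above the 75th percentile. In the Notch list the median was -0.01 (percentile 28.8), and the receptor Notch3 was lower (-1.14). Immediate early genes had a median of -0.13 (percentile 5.38), with 3 of 20 at least 2-fold lower, the transcription factors Fos (3.99-fold), Fosl2 (-1.49) and Klf4, and 2 higher, Myc and Fosl1.

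Inflammatory mediators were higher. Of 21 cytokine and chemokine genes 7 were at least 2-fold higher and 1, Il1f8 (interleukin 36 beta), lower, with a median of 0.72 (percentile 100): the alarmin Il33 by 3.97, Il24, an interleukin 10 family cytokine, by 4.03, with an uninjured value below the low-signal level, and the neutrophil chemoattractants Cxcl3 and Cxcl5 by 2.28 each. Il1b was higher by 0.94, less than 2-fold. Antimicrobial and alarmin genes were split, with 3 of 13 at least 2-fold higher, the iron-binding lactoferrin Ltf (3.29), the defensin Defb14 (2.75) and S100a9, and 2 lower, Pglyrp1 and Defb1 (median 0.09, percentile 63.1). Interferon-stimulated genes had a median of -0.25 (percentile 0.810) with 3 of 15 at least 2-fold lower and 2 higher. Irf1, an interferon-induced transcription factor (-1.36), the GTPase Gbp2 (-1.27) and Oasl1 were lower, and Usp18 (1.72) and Oas2 (1.14) were higher. Without the low-signal filter the median of the interferon list was 0.00, within random lists. Of 12 antigen presentation genes B2m alone passed 2-fold (1.03), with a median of -0.11 (percentile 3.67), and 0 of 8 complement genes did (median 0.10, percentile 68.0).

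Markers of other cell types, which compare the 2 arrays and cannot show what both hold alike, were mostly within random lists. Macrophage and monocyte markers lay just above them (median 0.25, percentile 98.6), but 11 of 13 were less than 2-fold apart, with Ly6c2 higher (2.75) and the integrin Itgam lower (-1.55). Against random lists not matched on expression this median stayed within. Neutrophil markers had a median of 0.14 (percentile 79.3) with Ltf and S100a9 (1.89) the 2 of 11 past 2-fold. Epithelial cells can also express both. The neutrophil list lay above random lists with its mean (0.50) and without the low-signal filter (median 0.15). Dendritic cell markers (median 0.09, percentile 59.0) had Epcam at 1.43, a gene of many epithelia, and 0 of 5 lymphocyte markers passed 2-fold (median 0.12, percentile 71.3). Measured were 13 of 19 macrophage, 11 of 21 neutrophil, 5 of 11 dendritic, 5 of 19 lymphocyte and 5 of 13 blood markers. Several lay near the low-signal level of 5.44 in both arrays, such as Ly6g (5.44 uninjured, 5.58 injured) and Tyrobp (5.49 uninjured, 5.70 injured). Small differences there cannot show whether these cells changed in number. Of 5 platelet and red blood cell markers Ppbp alone passed 2-fold, and the list median was -0.03 (percentile 24.3). Keratocyte and stromal genes had a median of 0.02 (percentile 25.7), with the proteoglycan Dcn (-1.31) and Aldh3a1, which is also an identity gene, lower. Endothelial markers had a median of 0.08 (percentile 53.2) with the collagen Col8a1 higher (1.40). Conjunctival and goblet cell markers had a median of 0.14 (percentile 79.5) with Krt8 and Krt19 higher and the goblet mucin Muc5ac lower (-1.26). The list members Krt13 (12.06 uninjured, 11.77 injured) and Krt4 (11.85 uninjured, 11.98 injured) were bright in both arrays. How much conjunctival epithelium both samples hold therefore stays open. The mixed list of melanocyte, nerve, lens and muscle markers had a median of 0.07 (percentile 51.4) with the small heat shock protein Cryab lower (-1.24).

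Several lists of metabolic and stress genes had higher medians with members in both directions. Glycolysis and hypoxia genes had a median of 0.73 (percentile 100). At least 2-fold higher were 7 of 21, among them the glycolytic enzymes Pfkp (2.04) and Pgk1 (1.99). The row used for Pgk1, 1 of 2 kept rows, is not numbered under the X chromosome, where the gene lies. Which locus gave this value is therefore uncertain. In this glycolysis and hypoxia list the hypoxia-responsive genes Egln3 (-3.18) and Ndrg1 (-1.45) were lower, while Vegfa (1.26) was higher. Oxidative phosphorylation genes had 0 of 23 past 2-fold (median 0.22, percentile 95.5). Lipid synthesis genes had a median of -0.02 (percentile 23.0) with the sterol sensor Insig1 lower (-1.41). In the list of NRF2 targets (median 0.35, percentile 99.5) 6 of 19 were at least 2-fold higher and 3 lower. The aldo-keto reductase Akr1b8 (2.29), the glutathione peroxidase Gpx2 (1.81) and the haem oxygenase Hmox1 (2.82-fold) stood against the glutathione transferase Gsta2 (-1.98), Gstm1 and the quinone reductase Nqo1, and with the mean of 0.30 the list lay within random lists. Chaperone and unfolded protein response genes had a median of 0.45 (percentile 99.7) with 4 of 16 at least 2-fold higher and 1, Hspb1, lower. These 4 were the heat shock protein Hsph1 (2.19), the asparagine synthetase Asns (2.10) and the mitochondrial chaperonins Hspd1 (1.58) and Hspe1 (1.05).

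Circadian clock genes were lower, with 6 of 17 at least 2-fold lower, 0 higher and a median of -0.45 (percentile 0.0300). The clock output factors Dbp (-2.26) and Tef (-1.43), the period gene Per3 (-1.63) and the nuclear receptor Nr1d1 (-1.62) were among them. Both epithelia were collected about 48 hours after wounding, and the hour of day is not given in the sources used here. Sensory and ion channel genes had a median of -0.17 (percentile 1.67), with the taurine transporter Slc6a6 (-1.30) the chloride cotransporter Slc12a2 (-1.28) and the sodium channel subunit Scnn1a lower and the channels Ano1 (1.87) and Kcnk1 (1.26) higher. That list lay within random lists with its mean (-0.085) and without the low-signal filter (-0.034). Genes often used as references were not level, with a median of 0.38 (percentile 98.3), and 9 of 12 were less than 2-fold apart. The transferrin receptor Tfrc (2.31), B2m and Pgk1, whose row is of uncertain locus, were at least 2-fold higher in the injured epithelium. Xist, the RNA of the inactive X chromosome, was lower (-1.05), while the Y-linked genes Kdm5d (0.06), Uty (0.22) and Eif2s3y (0.41) were less than 2-fold apart. Injured and fellow eyes of the same mice would give both arrays the same mix of animals. The labels name males and females for the series as a whole. The number and sex of the mice behind each array are not given in the sources used here. Whether the mix was the same could thus not be checked, and the Xist difference stays unexplained. The sex-linked list had a median of 0.14 (percentile 69.7).

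**Figure D3:**
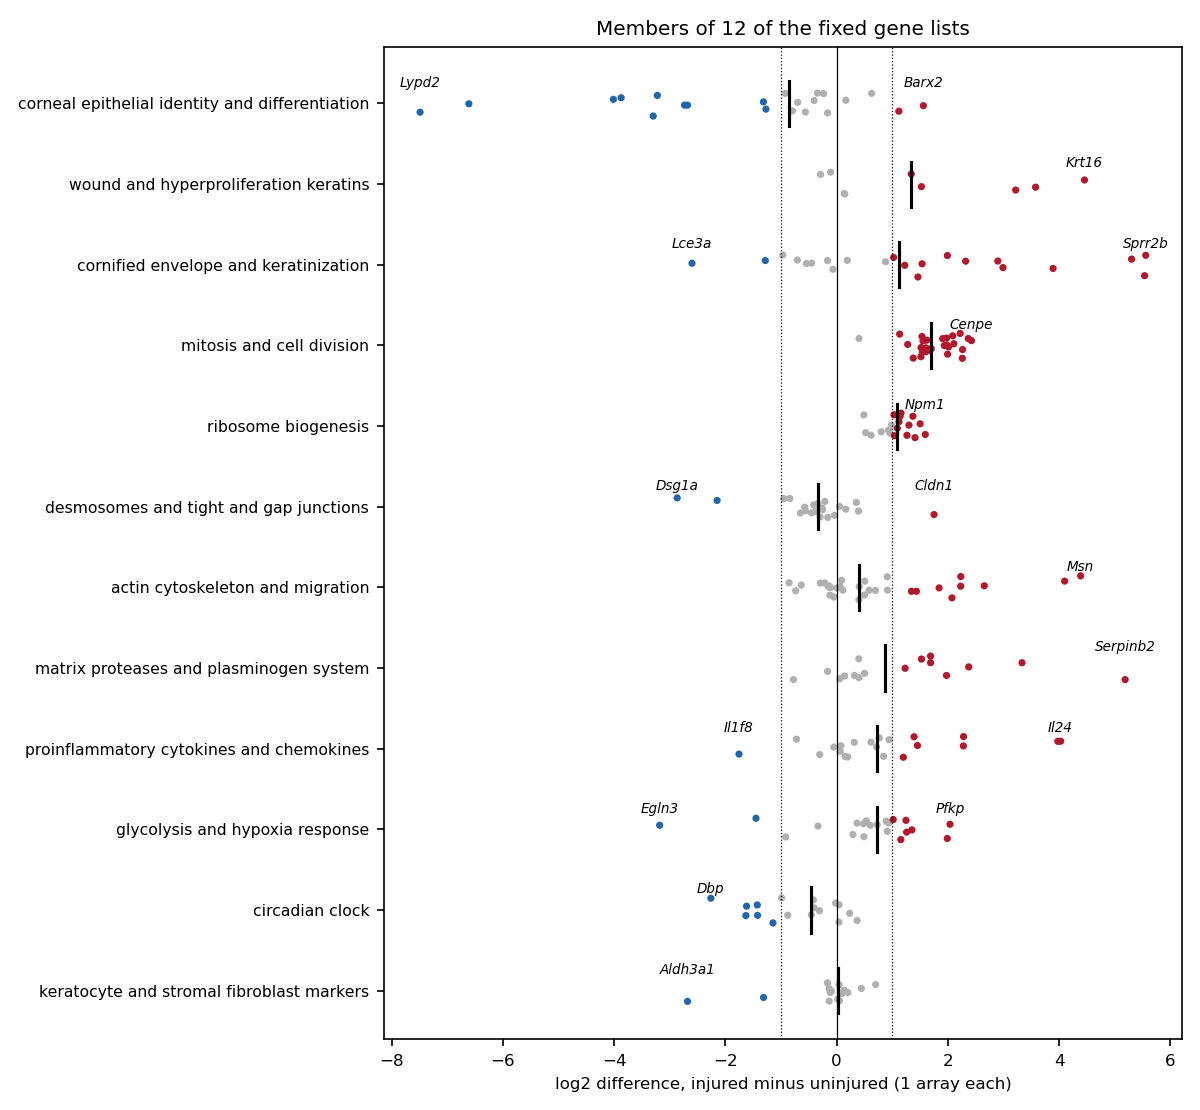
Log2 difference, injured minus uninjured, of each measured member of 12 of the fixed gene lists on the x axis, 1 array per group. Points are genes, red at least 2-fold higher, blue at least 2-fold lower and grey less than 2-fold apart. Black bars are list medians, and 26 of 27 mitosis genes lie beyond the 2-fold line while 13 of 15 stromal genes lie between the lines.

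Of 1286 measured long non-coding RNAs 11 were at least 2-fold higher (0.855%) and 23 at least 2-fold lower (1.79%). Shares depend on signal: among 186 of these RNAs with the brighter value above the 75th percentile 6 were higher (3.23%) and 15 lower (8.06%), and among 9046 protein-coding genes above it 608 were higher (6.72%) and 624 lower (6.90%). Above that level the highest RNAs were 2700038G22Rik (2.46), AI506816 (1.47), the snoRNA host gene Snhg5 (1.43), Gm36551 (1.32) and D730005E14Rik (1.16). The lowest were Xlr4d-ps (-4.28), Emx2os (-3.05), A830036E02Rik (-2.75), Zfp419 (-2.49) and Gm45351 (-2.12), with injured values of Xlr4d-ps (4.86) and Emx2os (4.96) below the low-signal level, so the size of both is uncertain. Wincr1 (2.34) lay below the 75th percentile and is not ranked. RefSeq lists Zfp419 as non-coding, and Xlr4d-ps belongs to a family of near-identical copies, so its signal can be shared. Emx2os runs antisense to the homeobox gene Emx2. Of 29 measured RNAs in the list of named long non-coding RNAs 28 were less than 2-fold apart (median 0.13, percentile 87.0). Malat1 differed by -0.65 and Neat1 by -0.03. A further 14035 unnamed rows passed the low-signal filter, of which 357 were at least 2-fold higher and 639 at least 2-fold lower. No row carries the name of the non-coding RNA in the series title, so it is not analysed here.

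Precision within the arrays can be read from genes measured by several rows. Rows of one gene differed from each other with an SD of 0.254 on the log2 scale, and for 84.8% of 230 such genes all rows lay on one side of 0. Of 21 such genes with a row at least 2-fold apart 90.5% had all rows on one side. Among 14919 rows with both values below the 25th percentile, 5 were at least 2-fold apart. Requiring both values to be that low removes rows with large differences, so this count is no measure of precision. The figures for rows of one gene cover measurement error within 2 arrays and leave out the spread between mice.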

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

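No result that lay past its threshold changed direction under any alternative run. Drawing random lists from protein-coding genes only was chosen after seeing the data, and the other alternatives were fixed before. The 2 arrays were level as deposited, so other scalings had little to correct. The 4 other scalings left between 1536 and 1551 of the 1561 genes that were at least 2-fold apart. With the brighter value above the 75th percentile 1424 of them were left, with both values at or above the median 1378, and with a constant added before log2 1333. Using the row with the second highest mean left 5 genes higher and 8 lower, and 0 and 0 long non-coding RNAs, since 248 genes have such a row. At 1.5-fold 2155 genes were higher and 1696 lower (40 and 47 long non-coding RNAs), and at 4-fold 137 and 151 (2 and 6). Long non-coding RNAs numbered 6 higher and 15 lower with the brighter value above the 75th percentile, and 6 and 12 with both values at or above the median, where fewer RNAs were tested. With the mean in place of the median 3 lists were lower than random lists. Some lists came to lie within random lists, and the cause was not tested. Without the low-signal filter these were basal and limbal progenitor markers (0.13), interferon-stimulated genes (0.00) and sensory and ion channel genes (-0.034). With the mean they were the epidermal growth factor family (-0.28), interferon-stimulated genes (-0.19), NRF2 targets (0.30) and sensory and ion channel genes (-0.085). With the brighter value above the 75th percentile they were epithelial to mesenchymal transition (0.44) and macrophage markers (0.55), without matching on expression macrophage markers (0.25), without members of more than 1 list basal markers (0.0935), and against protein-coding random lists sensory and ion channel genes (-0.17). Of the values of named genes under the alternatives 1159 stayed on their side of 2-fold and 6 did not, those of B2m, D730005E14Rik, Dcn, Dusp4 and Itga5. Other lists left the range of random lists. With the mean, other growth factors (0.42), antimicrobial genes (0.41), neutrophil markers (0.50) and platelet and red blood cell markers (1.49) lay above it. Without the low-signal filter neutrophil markers (0.15) lay above and antigen presentation (-0.11) below it. With the brighter value above the 75th percentile mucins (-0.29) and the Wnt list (-0.48) lay below it. Without matching on expression integrins (-0.14) and immediate early genes (-0.13) lay below and oxidative phosphorylation (0.22) above it. No paired analysis was possible because each group has 1 array. Signal limits the low end: 107 list genes, S100a8 among them, lay below the low-signal filter.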

Other observations

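All groups, genes and tests in this part were chosen after the values were seen, apart from the fixed gene lists that are named as such. Single genes were picked by their values, and for Mir184, Mir204, Trpm3, Cyp2b19, Ppp1r3c, Slc16a12, Piezo2, Casp4, Sema3c, Wincr1, Pax6os1, Emx2os, Ptgs2, Krtap22-2, Krtap7-1 and Gp5 the dimmer value lay below the low-signal level, so the size of their differences is uncertain. Of 12 gene families tried, 5 lay below random lists, 5 above and 2 within. Those above were Sprr (median 2.94), Cxcl (1.45), Mcm (1.11), Igfbp (0.54) and Serpinb (0.43). Those below were Cyp, Adh, Muc, Gstm (-0.49) and Aldh (-0.22). The measured Sprr genes and several Mcm, Cxcl and Igfbp genes also belong to the fixed lists. Their family medians are therefore no separate support for those lists, and similar copies within a family can share signal. Of 44 measured cytochrome P450 genes 12 were at least 2-fold lower, 1 higher and 31 less than 2-fold apart, with a median of -0.15, and the lower ones included Cyp2f2 (-3.89), Cyp2b19 (-3.07) and Cyp3a13 (-2.89). Of 5 alcohol dehydrogenase genes 4 were lower, Adh6b by 16.5-fold (-4.04) and Adh1 by 6.15-fold (-2.62). The 9 measured genes named Muc, 4 of them in the fixed mucin list, had a median of -1.13 with 5 at least 2-fold lower and 0 higher, below random lists, unlike that fixed list. Besides the glycogen-targeting subunit Ppp1r3c, the glycogen phosphorylase Pygl (-3.46) and the glycogenin Gyg (-3.12) were lower. So were Cdo1, which starts the oxidation of cysteine (-4.01), the glycine cleavage enzyme Gldc (-3.12), the carnitine palmitoyltransferase Cpt1a (-2.13) and the monocarboxylate transporter Slc16a12 (-4.33), while its relative Slc16a1 was higher (2.41). The mitochondrial folate enzymes Mthfd1l (5.67-fold) and Shmt2 (4.08-fold) and the proline synthesis enzyme Aldh18a1 (3.83-fold) were higher. Extracellular matrix genes of the Fraser complex, Frem2 (-3.40) and Fras1 (-3.05), and the mechanosensitive channel Piezo2 (-3.25) were lower.

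Among 470 measured microRNA rows 4 were at least 2-fold higher and 6 lower, Mir184 (-3.86) and Mir204 (-3.14) among the latter. Mir204 lies within Trpm3, which was also lower (-5.51). Some long non-coding RNAs differed in the direction of a neighbouring gene: Pax6os1 (-1.22) with Pax6 (-1.32), and Emx2os (-3.05) with Emx2 (-1.82). The long non-coding RNA Wincr1 was higher (2.34), with both values below the 75th percentile of the table. On the higher side stood the necroptosis genes Mlkl (2.30) and Ripk3 (1.69) with the inflammatory caspase Casp4 (2.13), and the TRAIL decoy receptors Tnfrsf23 (3.18) and Tnfrsf22 (2.09). The guidance cue Sema3c (3.04) was higher with the receptor Nrp2 (2.82), and the retinoic acid binding protein Crabp2 (4.11) with its relative Fabp5 (2.39). Prostaglandin E synthase, Ptges, was higher by 1.68 beside Ptgs2. Under the 4 other scalings none of the differences of single genes given here changed direction or dropped below 2-fold, apart from those of the keratin-associated genes, which were tried as a count. The 2 arrays were level as deposited, so these scalings moved values little and this outcome was likely beforehand. Of 27 measured keratin-associated protein genes 13 were at least 2-fold lower and 0 higher, as under each of the 4 scalings, and 10 of these 13 lie in a group of 11 neighbouring genes, including Krtap22-2 (-3.37) and Krtap7-1 (-3.23). The 22 hair keratin and hair follicle genes with a row, taken without the low-signal filter, ranged from -0.46 to 0.21. Genes dim in both arrays can hardly differ, so this range says little. Members of the keratin-associated group are similar enough to share signal.

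The fixed corneal identity list had a median of -0.86. A smaller share of epithelial cells with no other change would lower its genes alike. The 22 measured identity genes spanned 9.05, from Lypd2 at -7.49 to Barx2 at 1.56. A loss of superficial cells over unchanged basal cells would raise basal genes alike. The 7 measured basal genes spanned 3.42, from Krt14 at 2.23 to Krt15 at -1.20, with 1 at least 2-fold higher and 1 lower. So neither set moved alike in these 2 arrays. These ranges cannot decide, since the SD of 0.254 between rows of one gene leaves out the spread between mice. The difference over all genes had an SD of 0.614, so some spread was likely in any set of genes. How often random sets of genes reach ranges of 9.05 and 3.42 was not computed. Within these 2 arrays an equal lowering does not describe the identity genes, of which 10 were at least 2-fold lower and 2 higher. Whether a smaller epithelial share was part of the difference stays open, as does a loss of superficial cells. For the share of epithelial cells 4 other forms were computed first, and none is used: the 10 identity genes at least 2-fold lower (median -3.26) were picked by the values tested, the SD of 0.863 over single junction genes is no yardstick for medians, the gap of 0.52 between the junction list (-0.34) and the identity list had a central 95% over 10000 draws of genes from -0.0038 to 2.44 and did not decide, and the SD of 2.33 over the identity genes reads the same spread as the range. No biological explanation was tested, since stage of wound repair, collection and animal cannot be separated with 1 array per group.

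Ppbp was 146-fold higher and is best known from platelets. Platelets in the injured sample would bring their other transcripts, but 0 of 8 measured platelet genes other than Ppbp were at least 2-fold higher, with Gp5 at 0.64 and Pf4 at 0.55. A second possibility is that the genes around Ppbp are higher as a block. Of its 10 nearest measured protein-coding genes 4 were at least 2-fold higher, Cxcl5 (2.28), Cxcl3 (2.28), Cxcl1 (1.39) and Cxcl2 (1.45), a number that 0.614% of genes reach. That number fell short of the 5 set for a block. Pf4, itself a chemokine gene and 1 of these 10 neighbours, was less than 2-fold apart. A block, or shared control of only some of the chemokine genes, stays open.

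Of 986 unnamed rows at least 2-fold apart that have a numbered identifier, 41.9% had an adjacent unnamed row that differed in the same direction, against at most 4.87% in 1000 shuffles. Identifier numbers follow the order of genes for 99.3% of successive named rows, so neighbouring rows may measure pieces of one transcribed locus and the counts of unnamed rows may exceed the number of RNAs. The nearest named row differed by at least 2-fold in the same direction for 36.8% of these rows, above the highest shuffle at 7.30% but below the 50% set for unannotated parts of changed genes, which leaves the others open. Among 28 runs of 4 or more such rows, 22 lower and 6 higher, the longest had 20 rows with a median of -2.21 directly after the row of Auts2, itself lower (-1.24). A run of 11 rows with a median of -3.32 ended 2 rows before the row shared by Zbtb20 and Mir568 (-0.85), and a run of 9 rows with a median of 3.17 lay between Gm7658 (0.43) and Rims1 (0.22), both less than 2-fold apart.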
